A study of Dunaliella viridis with 88 samples.

How the data were processed

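RNA of Dunaliella viridis cultures was made into libraries with a TruSeq RNA kit after Trizol extraction and sequenced on an Illumina Genome Analyzer, per the labels' protocols. The deposited values are RPKM per lane, made by the authors; the submitters' processing notes name Bowtie, and how the loci were assembled and annotated is not given in the sources used here. Per the file headers each locus has a length, a protein description and GO terms. RPKM times length in kilobases sums to 1000000 per lane, and 100.0 percent of values are whole multiples of 1 read within a tolerance of 0.01, so reads per library were recovered. Recovered reads per library ran from 8137532 to 18189035. RPKM is relative to all reads on the 9400 loci, so a library rich in a few transcripts has lower values for the rest.

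Of the lane columns, 40 name their light condition and time at 25 °C and 48 carry only a number and a lane. The 48 columns were not used in any step. Columns of t3 to t5 match sample titles of both runs and were mapped to the condition only; that they are of the same run as t1 and t2 is an inference from a shared part of the names. The fits fixed before the data were examined needed a second library per condition at 25 °C and the 35 °C libraries, so they could not be made, and temperature is not analysed here. The values of the 4 lanes of each library were averaged and counted as 1 library.

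The fit used in their place was chosen after the values were seen, and its p-values are not those of a test fixed in advance. It takes the 8 libraries of t2 to t5, with 4 means (light by hour of the day) and a term for the later day, and leaves 3 residual degrees of freedom. Other forms were tried on the same values before it was chosen: 10 libraries with time points as blocks, with 4 means, or with 4 means and linear time, and the 8 libraries without the day term, each under deposited, median-ratio and quantile scaling, the fits of 8 libraries with the variance trend on and off, and voom under 2 scalings. These made 23 forms with the one kept, and the light mean of the fits of 10 libraries was first weighted by time points (0 to 182 loci). Over the 23 forms the counts were 0 to 2248 for light at t3 and t5, 110 to 3668 for light at t2 and t4, 5 to 1961 for the light mean and 86 to 3760 for the interaction. They were 2023 to 5030 for the hour effect in light/dark, 0 to 27 for that in continuous light and 0 to 58 for the later day. The fit of 8 libraries was kept because light, hour and day are balanced in it and because t1 may precede any difference in light. Deposited scaling was kept because it had been planned.

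Values were log2(RPKM + 1), so changes of low loci are understated, and loci with a mean of at least 1 RPKM over the 8 libraries were tested (9374 loci). Tests used limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with trend) with Benjamini-Hochberg adjustment and a threshold of 0.05. Under deposited scaling limma set the prior degrees of freedom to infinity, so all loci of one level share one variance, and single adjusted p-values are smaller than 2 libraries per mean can carry for loci that vary more than this. Under median-ratio scaling the prior degrees of freedom were 5.091, and those p-values are given beside the main ones for some loci.

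Named loci follow a rule fixed at the same stage as the planned fits: per test, the 5 largest rises and 5 largest falls at an adjusted p under 0.05, with a mean of at least 5 RPKM, the same direction in every matched pair and a description that names a protein, plus the 2 members with the smallest adjusted p of each list with at least 3 members past the threshold. A description reading anonymous locus was held to name no protein. The text names part of these. The 22 gene lists were keyword patterns fixed at that stage, counted over all loci and adjusted over the list alone, and tested with camera at a preset correlation of 0.01. A keyword match does not show that a locus has the function in the list's name. The carotenoid synthesis list, for example, also holds a carotenoid cleavage dioxygenase (locus 3322). With an estimated correlation, which rests on 3 residual degrees of freedom, none of the 22 lists passed in any comparison. Lists of chloroplast-encoded, mitochondria-encoded and nuclear photosystem loci were added later.

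The fit was tested on simulated reads for the comparison of hour 16 with hour 6 in light/dark, over 9374 loci with 200 changed, real library sizes and the measured chloroplast shares. With deposited scaling it recovered 2.4 percent of 1.5-fold, 52.2 percent of 2-fold and 99.4 percent of 4-fold changes, with 2.0 false calls on average. With median-ratio scaling it recovered 49.0, 90.4 and 99.7 percent, with 7.2 false calls. False calls were counted over unchanged loci without the chloroplast-encoded ones. All simulated loci shared the same dispersion, from the median residual SD of 0.12 on the log2 scale. Real loci may vary more and many more were called, so these false calls do not give a rate for the real data. The recovery under each scaling likewise holds for few changes, equally up and down, and not for the real data. Without the chloroplast shares in the simulation, deposited scaling recovered 62.4 percent and median-ratio scaling 61.8 percent of 1.5-fold changes. Alternatives covered the pseudocount, the filter, the scaling, the lane average, the form of the fit, voom on recovered reads and each library left out.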

Results

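The series measured transcripts of Dunaliella viridis, a unicellular green alga of salt water, in cultures kept in continuous light or in a cycle of 12 h light and 12 h dark. Samples were taken 6, 16, 30, 40 and 54 h after inoculation (t1 to t5). The labels also give a temperature factor of 25 and 35 °C, which is not analysed here because 48 columns of the deposited table carry no condition. The 10 libraries used were all from 25 °C, 1 per light condition and time, each sequenced in 4 lanes. By their names the columns of t1 and t2 match only titles of the second run, while those of t3 to t5 match titles of both runs. That all are of 1 run is taken from a shared part of their names, and if it is wrong, run is mixed with time. Recovered reads per library ran from 8137532 to 18189035 over 9400 loci. With 1 library per condition, libraries taken 24 h apart stand in as repeats: t2 and t4 (hour 16 of the day) and t3 and t5 (hour 6). An SD over 2 such libraries holds culture age and sampling differences together. All columns used carry the same replicate name, so an effect of light cannot be told apart from a difference between cultures. The p-values and SEs rest on the spread left after a term for the later day. Under deposited scaling that spread is shared by all loci of like level, so it does not follow the SD printed for a single locus. If the cycle began with light at inoculation, which the labels do not state, hour 16 fell in the dark period of the light/dark cultures.

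The first question was how far the cultures of the 2 light conditions differed at each time. At t1, 59 of 9375 loci differed by at least 2-fold, or 122 with a pseudocount of 0.1 RPKM. The early light-induced protein of locus 2256, a chloroplast protein of the light-harvesting family made under light stress, was at 368 RPKM in continuous light and 417 RPKM in light/dark at t1. The kinesin of locus 3068, a microtubule motor, stood at 1.69 and 2.63 RPKM. From t2 on the counts were larger, with 497 loci at least 2-fold apart at t2, 925 at t3, 779 at t4 and 638 at t5. Under median-ratio scaling the counts at t1 to t5 were 55, 502, 532, 826 and 581, so that t4 and not t3 was the highest. A pseudocount of 5 RPKM gave 36, 283, 449, 407 and 314. These counts compare single libraries, without a replicate at the same time. With log2(RPKM + 1) and deposited scaling, light/dark libraries 24 h apart differed at 146 (t3 and t5) and 76 loci (t2 and t4). In continuous light these counts were 122 and 116, and single lanes of the same library differed at 41 to 161 loci. The 59 loci at t1 lay within the range of the lanes, and the deposited counts at t2 to t5 lay above all of these. Libraries of t1 and t3, also 24 h apart, differed more, at 955 loci in continuous light and 509 in light/dark. The continuous light count lay above every count between lights, and the light/dark count lay above that at t2 only. With the first day included, the differences between lights therefore did not all exceed change over 24 h.

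Within the light/dark cultures, most flagellar loci and part of the cell cycle loci were higher at hour 16 than at hour 6. The kinesin of locus 3068 rose from 1.22 ± 0.379 to 167 ± 40.6 RPKM (SD, n = 2), a log2 change of 6.24 ± 0.29 (SE). The cyclin-dependent kinase regulatory subunit of locus 10565, which acts in cell-cycle progression, rose from 8.82 ± 1.03 to 519.7 ± 122 RPKM. The microtubule-bundling protein MAP65 of locus 2457 rose by 5.56 and plastid division protein 2 of locus 2129, part of the chloroplast division machinery, by 4.77 on the log2 scale. The early light-induced protein of locus 2256 fell from 1043 ± 104 to 4.41 ± 2.08 RPKM, a log2 change of -7.64 ± 0.36, and the carotene biosynthesis-related protein of locus 2154 changed by -5.40 ± 0.35.

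Of 251 flagellar loci, 199 rose and 0 fell (212 rose adjusted over the list alone), with a list median of 1.23 against 0.21 for all loci, and camera gave an adjusted p of 8.59e-20. The flagellar associated proteins of loci 5567 and 7553 rose by 4.07 ± 0.27 and 3.51 ± 0.30. Of 82 loci of cell cycle and DNA replication (list median 0.45), 28 rose and 1 fell (30 and 1 adjusted over the list alone; camera adjusted p = 2.19e-05), among them the condensin subunit of locus 15076, which compacts chromosomes, at 27.0 ± 0.836 RPKM against 0.0592 ± 0.0838 RPKM. Of 17 carotenoid synthesis loci, 6 fell and 1 rose, the riser being the carotene isomerase of locus 6763 at 1.69 ± 0.26 (the same counts adjusted over the list alone; camera adjusted p = 6.34e-04). Of 25 chlorophyll synthesis loci, 8 rose and 0 fell (10 rose adjusted over the list alone; camera adjusted p = 0.0737), with the magnesium chelatase subunit of locus 10698, at the entry to chlorophyll synthesis, at 4.54 ± 0.26. Light-harvesting loci moved both ways, 3 rising and 5 falling of 22 (3 higher and 5 lower adjusted over the list alone), with a median of 0.33, a mean of -0.47 and a camera direction downward at adjusted p = 7.30e-04. Under median-ratio scaling that camera p was 0.783. In starch metabolism 10 of 27 loci rose and 3 fell, led by the isoamylase of locus 5251, a debranching enzyme, at 12.1 ± 5.45 and 113 ± 19.2 RPKM at hour 6 and hour 16 (10 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.587; 13 higher and 7 lower under median-ratio scaling). In lipid breakdown 9 of 32 loci rose, led by the lipase precursor of locus 7995 at 2.21 ± 0.27 (11 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.285). Of 13 fatty acid synthesis loci 1 rose and 2 fell, with the omega-3 desaturase of locus 4592 at -1.36 ± 0.37 (1 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.324; 2 higher and 6 lower under median-ratio scaling). Under median-ratio scaling the numbers of higher and lower loci were 203 and 7 (flagella), 35 and 10 (cell cycle and DNA replication), 1 and 9 (carotenoid synthesis), 13 and 3 (chlorophyll synthesis), 4 and 6 (light harvesting) and 11 and 1 (lipid breakdown). With an estimated correlation every one of these lists had an adjusted p = 0.991.

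Across all loci, limma called 2478 of 9374 between hour 16 and hour 6 in light/dark at an adjusted p under 0.05, 1930 higher and 548 lower (77.9 percent higher). Under median-ratio scaling it called 4839, 2463 higher and 2376 lower (50.9 percent higher), and 2372 loci were called under both scalings. With 1 library left out the counts were 1121 loci without LD t2, 983 without LD t4 and 4626 without LD t5. By direction there were 1676 higher and 1808 lower without LD t3, and 4238 higher and 388 lower without LD t5 (3484 in all without LD t3). Without LD t3 and CL t5 there were 1726 and 1681. Fits of all 10 libraries, with t1 taken as hour 6, called 2391 with day terms, 2960 with linear time and 2023 with 4 means and no term for time. LD t3 held 29.45 percent of its reads on chloroplast-encoded loci. The chloroplast-encoded photosystem II 44 kDa protein of locus 12564 was at -1.67 ± 0.27 under deposited scaling and -1.87 ± 1.31 (SE) under median-ratio scaling, where the call ended (adjusted p = 0.265) because the SE was larger, and at 0.81 without LD t3.

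In continuous light fewer loci were called between the same hours. The flagellar list had 0 of 251 loci past the threshold and a median of 0.17 against 0.21 for all loci, and the cell cycle list 0 of 82 (0 flagellar loci, and 1 cell cycle locus higher, adjusted over the list alone). Limma called 27 loci, 9 higher and 18 lower, at hour 16 against hour 6. The chloroplast-encoded J protein of photosystem II of locus 16710 was lower at -1.36 ± 0.26, as was the D2 protein of locus 16930 at -1.61 ± 0.29, while the glyceraldehyde-3-phosphate dehydrogenase of locus 203, a glycolytic enzyme, was higher at 1.24 ± 0.30. CL t5 held 25.14 percent of its reads on chloroplast-encoded loci, and under median-ratio scaling limma called 0 loci, with 654 at an unadjusted p under 0.05. Limma voom on recovered reads called 15. Fits of 10 libraries called 100 with day terms, 2 with linear time and 0 with 4 means and no term for time. Leaving out 1 library gave 0 loci without CL t2, 57 without CL t3, 16 without CL t4, 6 without CL t5, 8 without LD t2, 292 without LD t3, 8 without LD t4 and 298 without LD t5. Locus 16710 stood at 0.24 without CL t5.

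The difference between the 2 light conditions in this hour effect was tested directly. The log2 difference, light/dark minus continuous light, was 6.55 ± 0.41 for the kinesin of locus 3068, 5.53 ± 0.38 for MAP65 of locus 2457 and 5.18 ± 0.50 for the cyclin-dependent kinase regulatory subunit of locus 10565. It was -8.58 ± 0.50 for the early light-induced protein of locus 2256, -6.04 ± 0.50 for the carotene biosynthesis-related protein of locus 2154 and -5.54 ± 0.51 for the CAB/ELIP/HLIP family protein of locus 1906. Of 251 flagellar loci, 117 had a larger hour 16 rise in light/dark and 0 a smaller one (150 adjusted over the list alone; camera adjusted p = 9.62e-20, and adjusted p = 0.989 with an estimated correlation). The cell cycle list gave 18 and 0 of 82 (18 and 1 adjusted over the list alone), the chlorophyll synthesis list 5 and 0 of 25, and the carotenoid list 1 and 6 of 17. For the last pair these were 5 higher and 0 lower adjusted over the list alone, and 1 higher and 7 lower adjusted over the list alone. Higher and lower loci under median-ratio scaling numbered 180 and 3 (flagella), 27 and 4 (cell cycle and DNA replication), 13 and 3 (chlorophyll synthesis) and 1 and 9 (carotenoid synthesis). The isoamylase of locus 5251 differed by 3.41 ± 0.43, the chloroplastic-like isoamylase of locus 2268 by -2.41 ± 0.49, and the glutathione peroxidase of locus 7108, which removes peroxides, by -2.72 ± 0.51. In all, limma called 1280 loci, 829 higher and 451 lower (64.8 percent higher), and 3622 under median-ratio scaling, 1903 higher and 1719 lower (52.5 percent higher), with 1260 called under both. In fits of all 10 libraries, with t1 taken as hour 6, the count was 1177 with day terms, 813 with time points as blocks, 921 with linear time and 86 with 4 means and no term for time. Leaving out 1 library gave 507 loci without CL t2, 441 without CL t4, 565 without LD t2, 3233 without LD t3, 460 without LD t4 and 2666 without LD t5. By direction these were 1085 higher and 2148 lower without LD t3, and 2135 higher and 531 lower without LD t5.

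At t3 and t5, part of the cell cycle and flagellar loci were higher in continuous light than in light/dark. The cyclin-dependent kinase regulatory subunit of locus 10565 was at 251 ± 63.3 RPKM in continuous light and 8.82 ± 1.03 RPKM in light/dark, a log2 change of 4.66 ± 0.35 with an adjusted p of 5.86e-37 (2.86e-06 under median-ratio scaling). The E3 ubiquitin ligase RFWD3 of locus 16515 was higher by 2.65 ± 0.27. Lower in continuous light were the early light-induced protein of locus 2256 at -2.12 ± 0.36, the chlorophyll a-b binding protein of locus 3087, a light-harvesting antenna protein, at -1.91 ± 0.27, and the adenylate/guanylate cyclase of locus 6421 at -1.79 ± 0.26. Of 251 flagellar loci 71 rose and 0 fell in continuous light (105 adjusted over the list alone; camera adjusted p = 2.01e-12), and of 82 cell cycle loci 20 rose and 0 fell (23 adjusted over the list alone; camera adjusted p = 3.27e-09). Of 110 loci of mobile elements, viruses and bacteria, 20 fell and 2 rose, with the Ty3-gypsy retrotransposon of locus 10259 at -1.48 ± 0.27 (2 higher and 34 lower adjusted over the list alone; camera adjusted p = 8.93e-12). Of 93 heat shock and chaperone loci 12 rose, with the HSP90 family protein of locus 848 at 2.42 ± 0.26 (12 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.769). Under median-ratio scaling 11 of the 93 rose and 14 fell (camera adjusted p = 0.852, direction downward). With median-ratio scaling, higher and lower loci numbered 127 and 3 (flagella), 34 and 2 (cell cycle and DNA replication) and 1 and 45 (mobile elements, viruses and bacteria). With an estimated correlation each list had an adjusted p = 0.996. Limma called 712 loci, 545 higher and 167 lower (76.5 percent higher), against 2232 under median-ratio scaling, 1208 higher and 1024 lower (54.1 percent higher), with 671 called under both. With t1 taken in as hour 6, the count was 418 with day terms, 292 with time points as blocks, 188 with linear time and 0 with 4 means and no term for time. The last 3 of these forms gave 0 under median-ratio or quantile scaling. Fits short of 1 library called 431 loci without CL t2, 333 without CL t3, 427 without CL t4, 467 without CL t5, 442 without LD t2, 1724 without LD t3, 448 without LD t4 and 2724 without LD t5. These were 592 higher and 1132 lower without LD t3, and 2518 higher and 206 lower without LD t5.

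At t2 and t4, part of the loci of the carotenoid synthesis list were higher in continuous light, and part of the chlorophyll synthesis, photosystem and flagellar loci were lower. The early light-induced protein of locus 2256 was at 461 ± 94.8 RPKM in continuous light and 4.41 ± 2.08 RPKM in light/dark, a log2 change of 6.46 ± 0.36. The carotene biosynthesis-related protein of locus 2154 was higher by 5.26 ± 0.35, and the photosystem II-associated 22 kDa protein of locus 2540, which takes part in heat dissipation, by 2.39 ± 0.38. The major light-harvesting chlorophyll a/b protein of locus 1 was lower, at 258 ± 215 against 1856 ± 432 RPKM, as were phosphoenolpyruvate carboxykinase of locus 5920, an enzyme of gluconeogenesis, at -3.30 ± 0.28 and cytosolic phosphoglucose isomerase of locus 13991 at -2.49 ± 0.27. Of 25 chlorophyll synthesis loci 7 fell and 0 rose in continuous light (7 and 1 adjusted over the list alone; camera adjusted p = 5.80e-04), with uroporphyrinogen decarboxylase of locus 2986 at -1.39 ± 0.33. Of 22 light-harvesting loci 4 rose and 6 fell (6 higher and 12 lower adjusted over the list alone; camera adjusted p = 0.61). Of 44 photosystem and electron transport loci 7 fell and 2 rose (2 higher and 13 lower adjusted over the list alone; camera adjusted p = 5.80e-04). Of 17 loci of the carotenoid synthesis list 6 rose and 0 fell (7 higher and 0 lower adjusted over the list alone, camera adjusted p = 4.83e-06). Its members with the smallest adjusted p were locus 2154 and the carotenoid cleavage dioxygenase of locus 3322 (2.16 ± 0.33), so the list does not stand for synthesis alone. Of 251 flagellar loci 36 fell and 1 rose (1 higher and 51 lower adjusted over the list alone; camera adjusted p = 7.72e-14). In light and clock signalling 4 of 18 rose, with the 6-4 photolyase of locus 5366, a DNA repair enzyme or cryptochrome relative, at 1.30 ± 0.29 (4 higher and 0 lower adjusted over the list alone). Median-ratio scaling gave these numbers of higher and lower loci: 3 and 17 (chlorophyll synthesis), 5 and 12 (light harvesting), 5 and 19 (photosystems and electron transport), 9 and 1 (carotenoid synthesis), 6 and 144 (flagella) and 7 and 0 (light and clock signalling). Each list had an adjusted p = 0.939 with an estimated correlation. Limma called 910 loci, 428 higher and 482 lower, and 3557 under median-ratio scaling, 1730 higher and 1827 lower, with 880 called under both. The larger side turned to 1945 higher and 1723 lower under quantile normalization. With chloroplast-encoded loci left out of the totals it was 1988 higher and 1444 lower. Taking t1 in as hour 6 gave 996 with day terms, 594 with time points as blocks, 704 with linear time and 110 with 4 means and no term for time. With single libraries left out limma called 167 loci without CL t2, 109 without CL t4, 162 without LD t2, 3128 without LD t3, 99 without LD t4 and 3130 without LD t5.

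Averaged over t2 to t5, the glyceraldehyde-3-phosphate dehydrogenase of locus 203 was higher in continuous light (2.79 ± 0.21). So were the ferric-chelate reductase of locus 1615, which takes part in iron uptake (2.50 ± 0.19), and HSP90 of locus 848 (1.96 ± 0.19). In continuous light locus 203 varied widely, at 77.4 ± 76.2 RPKM at hour 6 and 157 ± 118 RPKM at hour 16 (SD, n = 2). At hour 16 locus 1615 was at 11.6 ± 10.0 and locus 848 at 16.9 ± 15.4 RPKM. Under median-ratio scaling their limma adjusted p-values for the light mean were 4.36e-04, 0.00236 and 0.013. The major light-harvesting protein of locus 64 was lower by -1.80 ± 0.28 and the alcohol dehydrogenase of locus 7135 by -1.22 ± 0.23. Of 82 cell cycle loci 14 rose and 0 fell (17 higher and 0 lower adjusted over the list alone; camera adjusted p = 1.97e-06), of 40 glycerol and salt loci 3 fell, with the sodium/phosphate symporter of locus 11294 at -0.83 ± 0.21 (0 higher and 4 lower adjusted over the list alone; camera adjusted p = 8.96e-04). Of 251 flagellar loci 3 rose and 1 fell (1 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.904). With an estimated correlation these lists had an adjusted p = 0.987. In fatty acid synthesis and glycerolipid assembly 0 of 13 and 0 of 10 loci passed under deposited scaling, as also when adjusted over the list alone. Median-ratio scaling gave these numbers of higher and lower loci: 31 and 2 (cell cycle and DNA replication), 0 and 12 (glycerol and salt), 9 and 21 (flagella), 2 and 1 (fatty acid synthesis) and 1 and 2 (glycerolipid assembly). Limma called 424 loci, 257 higher and 167 lower, and 1961 under median-ratio scaling. The fits of 10 libraries called 297 with day terms, 180 with time points as blocks, 90 with linear time and 8 with 4 means and no term for time. Leaving out 1 library gave 176 loci without CL t2, 225 without CL t3, 178 without CL t4, 183 without LD t2, 1135 without LD t3, 168 without LD t4 and 3350 without LD t5. There were 367 higher and 768 lower without LD t3, and 2958 higher and 392 lower without LD t5.

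Between one day and the next (t4 and t5 against t2 and t3), few loci were called. The low-CO2 inducible protein of locus 1717 rose by 3.51 ± 0.23 with an adjusted p of 7.59e-48 (0.0472 under median-ratio scaling), and the carbonic anhydrases of loci 1065 and 1180, which interconvert carbon dioxide and bicarbonate, rose by 1.60 ± 0.27 and 1.45 ± 0.26 (0.0574 and 0.0472 under median-ratio scaling). The 12-oxophytodienoic acid reductase of locus 4762 fell by 0.80 ± 0.20 and the superoxide dismutase of locus 11315, which removes superoxide, by 1.25 ± 0.19. Of 25 carbon fixation loci 3 rose and 0 fell, with 1 higher under median-ratio scaling (3 higher and 0 lower adjusted over the list alone; camera adjusted p = 9.55e-06, and adjusted p = 0.999 with an estimated correlation). Limma called 47 loci, 29 higher and 18 lower, and 33 under median-ratio scaling, of which 15 were shared. With the variance trend off it called 48 under deposited scaling and 0 under median-ratio or quantile scaling. Without LD t3 and CL t5 the count was 172. The count moved with single libraries, to 13 loci without CL t2, 13 without CL t4, 20 without LD t2, 1454 without LD t3, 20 without LD t4 and 1442 without LD t5. Of these, there were 119 higher and 1335 lower without LD t3, and 121 higher and 1321 lower without LD t5.

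Libraries also differed in how much chloroplast-encoded RNA they held. The share of reads on 30 such loci was 29.45 percent in LD t3 and 25.14 percent in CL t5, against 2.06 percent in LD t5 and 1.04 percent in CL t3. This share is a sum over loci of very unlike level, and the parts held by single loci, such as locus 25 below, were not separated. As a median over the 30 loci, levels relative to the median library were 6.77 in LD t3, 4.68 in CL t5, 0.84 in LD t5 and 0.31 in CL t3. The intron-encoded homing endonuclease of locus 25, annotated within ribosomal RNA, averaged 22358 ± 27489.5 RPKM at hour 6 in light/dark, and the photosystem I P700 apoprotein A1 of locus 6149 averaged 1589.8 ± 2004 RPKM. The mean share was 7.49 percent ± 10.1 (SD, n = 5) in continuous light and 8.32 percent ± 12.1 (SD, n = 5) in light/dark, an exact two-sided permutation p of 0.825, and for hour 6 against hour 16 the exact permutation p was 0.338. These tests could not decide, and a comparison of CL t5 with CL t3 was added after they were seen. The chloroplast list was drawn up after the values were seen, in part from loci high in LD t3.

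**Figure D1:**
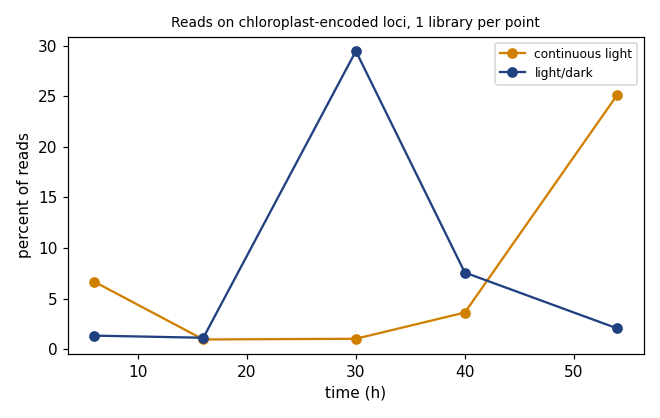
Percent of reads on chloroplast-encoded loci against time in h, 1 library per point, continuous light in orange and light/dark in blue. LD t3 at 29.45 percent and CL t5 at 25.14 percent stand above the other 8 libraries, the next being LD t4 at 7.58 percent. The share is a sum over loci and does not show which of them carry it.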

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

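The tests of the patterns below were chosen after the results were seen, except that of length and level.

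The hour effect differed between light conditions at 1280 loci by the interaction test. The largest differences, light/dark minus continuous light, were 6.55 for the kinesin of locus 3068, 5.53 for MAP65 of locus 2457, 5.18 for the cyclin-dependent kinase regulatory subunit of locus 10565, 4.79 for the kinetoplast-associated protein of locus 12323 and 4.62 for the ATP-binding protein of locus 1585. On the other side were -8.58 for the early light-induced protein of locus 2256, -6.04 for the carotene biosynthesis-related protein of locus 2154, -5.54 for the CAB/ELIP/HLIP protein of locus 1906, -5.22 for the short-chain dehydrogenase of locus 14127 and -4.85 for the follistatin-like protein of locus 3576. In CL t1, a library outside the fit, 6.67 percent of reads lay on chloroplast-encoded loci, against 1.35 percent in LD t1.

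The flagellar list rose at hour 16 in light/dark. Scaling of the libraries is argued against as the whole cause, since the list median stayed at 1.01 under median-ratio scaling, where the median of all loci was near 0. Locus length and level are argued against too: 0 percent of 10000 random lists matched on both reached that median, the highest being 0.13. Hour of sampling alone is argued against over t2 to t5 only, by the list median of -0.04 in continuous light. The first day is not covered by that value. In continuous light the flagellar associated protein of locus 5567 stood at 2.44 RPKM at t1 and 20.6 RPKM at t2. Over all loci, 868 were at least 2-fold higher and 154 lower at t2 than at t1 in continuous light. For t2 to t5, a response of flagellar genes to the light/dark regime may be the source. This is a hypothesis found and tested on the same libraries, with 1 culture per condition, and time since inoculation stays open for the first day.

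Chloroplast-encoded RNA was high in LD t3 and CL t5, by a list drawn up after the values were seen. For CL t5, light and hour of the cycle are argued against as the whole cause, because CL t5 and CL t3, of the same light and hour, differed 24.2-fold in share; for LD t3 they stay open, since the list was drawn up in part from loci high in that library. This comparison replaced permutation tests on the same shares (exact p = 0.825 for light and 0.338 for hour), which could not decide. Organelle RNA carried over in library making may account for it: the mitochondria-encoded loci were also raised, 2.02-fold in LD t3 and 2.96-fold in CL t5 over their median library, while nuclear photosystem loci stood at 0.71 and 0.95. A real rise of organelle transcripts in these cultures predicts the same and stays open, and in CL t1 the chloroplast list was at 5.00 but the mitochondrial list at 1.17.

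Calls leaned to higher values at hour 16 in light/dark (1930 higher and 548 lower) and at t3 and t5 (545 and 167). With chloroplast-encoded loci left out of the totals the calls were 2533 higher and 2172 lower (53.8 percent higher) and 1365 higher and 785 lower. The share fell because lower calls rose, while higher calls rose as well, so this test does not decide whether these loci in the totals made the lean. Without LD t3 the calls were 1676 higher and 1808 lower at hour 16, and 592 higher and 1132 lower at t3 and t5. Without LD t5, which leaves LD t3 alone at hour 6, they were 4238 higher and 388 lower, and 2518 higher and 206 lower; the source of the lean stays open.

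Other splits of the 8 libraries were run in the same form of fit. For the light mean, 3 of 32 splits, the real one among them, called at least the real 424 loci, the highest other calling 1280. That split is the one of light crossed with hour, a structure of these samples. The remaining split called 628 and set LD t3 and CL t5, the libraries richest in chloroplast-encoded RNA, on the same side. Since both reflect differences between these libraries, the count of splits does not measure chance, and chance cannot be excluded. For the later day, 13 of 32 splits, again with the real one counted, called at least 47, the highest other calling 97, and chance cannot be excluded.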

How the results depend on the processing

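No paired analysis was possible by replicate number, because all columns used carry the same one; the lights were paired by time point in the fits with time points as blocks, given below. The alternatives of run as a term and all 22 libraries were not run, since the columns they need carry no condition. A count test with edgeR was not run, since the deposited unit is RPKM, and voom on recovered reads was run in its place. The fits of 10 libraries, voom, the fits without the day term or variance trend, that without LD t3 and CL t5, and that with chloroplast-encoded loci left out of the totals were chosen after seeing the data. The cause of a changed count was not tested unless stated. In simulation with the measured chloroplast shares, median-ratio scaling recovered more changes of less than 4-fold. Only 200 of 9374 loci were changed there, equally up and down, so it does not show which scaling recovers more in the real data. Under median-ratio scaling, counts were 2232 (light at t3 and t5), 3557 (light at t2 and t4), 1961 (light mean t2 to t5), 3622 (the hour effect between lights), 4839 (the hour effect in light/dark), 0 (the hour effect in continuous light), 532 (loci over 2-fold between lights at t3). Under quantile normalization, counts were 2248 (light at t3 and t5), 3668 (light at t2 and t4), 1924 (light mean t2 to t5), 3760 (the hour effect between lights), 5030 (the hour effect in light/dark), 0 (the hour effect in continuous light), 527 (loci over 2-fold between lights at t3). Fits of 10 libraries with t1 gave 418 (light at t3 and t5), 100 (the hour effect in continuous light). Fits of 10 libraries with time points as blocks gave 292 (light at t3 and t5), 594 (light at t2 and t4), 180 (light mean t2 to t5), 813 (the hour effect between lights). Fits of 10 libraries with 4 means gave 0 (light at t3 and t5), 110 (light at t2 and t4), 8 (light mean t2 to t5), 86 (the hour effect between lights), 0 (the hour effect in continuous light). Fits of 10 libraries with linear time gave 188 (light at t3 and t5), 90 (light mean t2 to t5), 2 (the hour effect in continuous light). Counts with 10 libraries with time points as blocks and median-ratio scaling were 0 (light at t3 and t5), 2151 (light at t2 and t4), 211 (light mean t2 to t5), 2111 (the hour effect between lights). Counts with 10 libraries with 4 means and median-ratio scaling were 0 (light at t3 and t5), 520 (light at t2 and t4), 5 (light mean t2 to t5), 353 (the hour effect between lights), 0 (the hour effect in continuous light). Counts with 10 libraries with linear time and median-ratio scaling were 0 (light at t3 and t5), 1966 (light at t2 and t4), 2038 (the hour effect between lights), 4618 (the hour effect in light/dark), 0 (the hour effect in continuous light). Counts with 10 libraries with time points as blocks and quantile scaling were 0 (light at t3 and t5), 2308 (light at t2 and t4), 2434 (the hour effect between lights). Counts with 10 libraries with 4 means and quantile scaling were 0 (light at t3 and t5), 13 (light mean t2 to t5), 495 (the hour effect between lights), 0 (the hour effect in continuous light). Counts with 10 libraries with linear time and quantile scaling were 0 (light at t3 and t5), 2175 (light at t2 and t4), 2277 (the hour effect between lights), 4860 (the hour effect in light/dark), 0 (the hour effect in continuous light). With no day term and median-ratio scaling, counts were 1447 (light at t3 and t5), 2583 (light at t2 and t4), 831 (light mean t2 to t5), 2774 (the hour effect between lights), 4154 (the hour effect in light/dark), 0 (the hour effect in continuous light). With no variance trend and median-ratio scaling, counts were 2000 (light at t3 and t5), 3367 (light at t2 and t4), 1642 (light mean t2 to t5), 3493 (the hour effect between lights), 4775 (the hour effect in light/dark), 0 (the hour effect in continuous light), 0 (24 h later). With no day term or variance trend and median-ratio scaling, counts were 1294 (light at t3 and t5), 2374 (light at t2 and t4), 719 (light mean t2 to t5), 2603 (the hour effect between lights), 4092 (the hour effect in light/dark), 0 (the hour effect in continuous light). With no day term and quantile scaling, counts were 1425 (light at t3 and t5), 2628 (light at t2 and t4), 776 (light mean t2 to t5), 2862 (the hour effect between lights), 4331 (the hour effect in light/dark), 0 (the hour effect in continuous light). With no variance trend and quantile scaling, counts were 2047 (light at t3 and t5), 3496 (light at t2 and t4), 1678 (light mean t2 to t5), 3638 (the hour effect between lights), 4933 (the hour effect in light/dark), 0 (the hour effect in continuous light), 0 (24 h later). With no day term or variance trend and quantile scaling, counts were 1260 (light at t3 and t5), 2439 (light at t2 and t4), 666 (light mean t2 to t5), 2740 (the hour effect between lights), 4259 (the hour effect in light/dark), 0 (the hour effect in continuous light). With voom on recovered reads and median-ratio scaling, counts were 2213 (light at t3 and t5), 3551 (light at t2 and t4), 1914 (light mean t2 to t5), 3608 (the hour effect between lights), 4771 (the hour effect in light/dark), 0 (the hour effect in continuous light), 31 (24 h later). With chloroplast-encoded loci left out of the totals, counts were 2150 (light at t3 and t5), 3432 (light at t2 and t4), 2200 (light mean t2 to t5), 3507 (the hour effect between lights), 4705 (the hour effect in light/dark), 0 (the hour effect in continuous light). In the fit without the LD t3 and CL t5 libraries, counts were 3212 (light at t2 and t4), 1969 (the hour effect between lights), 172 (24 h later). With voom on recovered reads, counts were 15 (the hour effect in continuous light). With a pseudocount of 0.1 RPKM, counts were 122 (loci over 2-fold between lights at t1). With a pseudocount of 5 RPKM, counts were 36 (loci over 2-fold between lights at t1), 283 (loci over 2-fold between lights at t2), 449 (loci over 2-fold between lights at t3), 407 (loci over 2-fold between lights at t4), 314 (loci over 2-fold between lights at t5). With a mean of at least 5 RPKM, counts were 38 (loci over 2-fold between lights at t1). Leaving out each library in turn gave 333 to 2724 (light at t3 and t5), 99 to 3130 (light at t2 and t4), 168 to 3350 (light mean t2 to t5), 441 to 3233 (the hour effect between lights), 983 to 4626 (the hour effect in light/dark), 0 to 298 (the hour effect in continuous light), 13 to 1454 (24 h later), the lone library of a condition being assumed to vary like the others.

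Of 7094 values of 196 named locus results under the alternatives, 5766 kept their direction and side of the threshold, 1291 lost the call (227 of them with 1 library left out) and 37 turned sign. Among log2 values for light at t3 and t5, locus 18679 was -3.29 to 0.87 with 1 library left out, locus 6149 was -4.72 to 2.02 with 1 library left out and 0.14 in fits of 10 libraries with quantile scaling, locus 18428 was -3.45 to 1.48 with 1 library left out and 0.42 in fits of 10 libraries and 0.40 in fits of 10 libraries with median-ratio scaling and 0.31 in fits of 10 libraries with quantile scaling and 0.12 with voom on recovered reads and median-ratio scaling. Among log2 values for light mean t2 to t5, locus 6149 was -2.90 to 0.46 with 1 library left out, locus 18428 was -2.17 to 0.29 with 1 library left out. For the hour effect in light/dark, locus 12564 was -4.16 to 0.81 with 1 library left out and 0.41 without the LD t3 and CL t5 libraries, locus 18428 was -3.56 to 1.37 with 1 library left out and 0.85 without the LD t3 and CL t5 libraries, locus 18676 was -3.29 to 1.29 with 1 library left out and 0.91 without the LD t3 and CL t5 libraries, locus 25 was -4.97 to 2.04 with 1 library left out and 0.084 in fits of 10 libraries with quantile scaling and 0.14 in fits of 10 libraries with quantile scaling and 1.67 without the LD t3 and CL t5 libraries. For the hour effect in continuous light, locus 18704 was -2.87 to 0.048 with 1 library left out, locus 16710 was -2.96 to 0.24 with 1 library left out, locus 18676 was -3.00 to 0.54 with 1 library left out.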

Other observations

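The tests here were chosen after the data were seen. Among 5373 tested loci with GO terms, the 979 that were higher at hour 16 in light/dark under both scalings held 120 of 148 loci of the flagellum term (27 expected; one-sided hypergeometric adjusted p = 8.93e-62 over 292 terms). They also held 26 of 29 loci of the dynein complex (5.28 expected; adjusted p = 5.49e-15) and 46 of 67 of microtubule-based movement (12.2 expected; adjusted p = 9.73e-18). The 309 lower loci held 22 of 126 loci of helicase activity (7.25 expected; adjusted p = 0.000206), 13 of 69 of heat shock protein binding (3.97 expected; adjusted p = 0.00443) and 6 of 22 of rRNA processing (1.27 expected; adjusted p = 0.0311). The GO term names are from general knowledge, as the table gives only term numbers. Loci are not independent replicates, so these values describe these libraries.

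The 2372 loci called under both scalings at hour 16 in light/dark gave a scale on which light/dark hour 6 averages 0 and hour 16 averages 1. On it the t1 libraries, which played no part in setting the scale, both stood at -0.07. The continuous light libraries stood at 0.56 (t2), 0.51 (t3), 0.52 (t4) and 0.60 (t5), between the light/dark cultures of hour 6 and hour 16. The light/dark libraries set the scale, so their own places on it test nothing.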
